A study of Gallus gallus with 8 samples.

How the data were processed

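Skin from 2 body sites of 9-week-old chickens was compared on one-colour expression arrays. There were 8 samples, 4 of dorsal skin and 4 of leg skin, with 1 array per sample. Per the series design text, 4 chickens supplied skin from both sites; the labels number the samples of each site from 1 to 4 but do not state that equal numbers mark the same chicken. Per the labels' protocols, the skin was frozen in liquid nitrogen, total RNA was extracted with a column kit, amplified, labelled with Cy3 and hybridised to a long-oligonucleotide chicken array.

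Per the file headers, each array was scanned and read with Agilent Feature Extraction 10.7.1.1, which gave for every spot the mean pixel intensity, the median local background intensity, and a processed intensity from which background and spatial trends had been removed within the array, with no normalization between arrays. Per the file headers, the deposited files also carry flags of 0 or 1 for spots that were well above background, positive and significant, saturated or outliers. The deposited series table holds log2 values. In each of its columns the median was 7.43 and the upper quartile 9.94, as quantile normalization gives; the method is not given in the sources used here. The correlation of each column with its own array's log2 processed intensity over 43603 probes was 0.996 or higher, and the highest with any other array was 0.985, so its rows and columns match the scanner files. Its scale and direction are therefore known, and its normalization method stays unknown.

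Each array had 45220 spots, which covered 43603 different probes once control spots were left out. Spots with an outlier flag, 4 to 10 per array, were left out, and spots of one probe were averaged. No probe was saturated. The share of probes well above background was 79.3%, 81.1%, 82.0% and 81.0% in dorsal skin samples 1 to 4, and 75.5%, 78.0%, 79.1% and 89.3% in leg skin samples 1 to 4. The number of arrays limits the precision.

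Values were log2 of the processed intensity minus each array's 75th percentile, so a printed level is in log2 units relative to that percentile. Probes well above background on at least 4 of the 8 arrays were tested, 35516 in all. Leg skin was compared with dorsal skin in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, a two-sided moderated test with site as its only term, and p-values were adjusted by the Benjamini-Hochberg method over all probes tested. The threshold was an adjusted p of 0.05. Standard errors are those of limma's moderated fit, and differences are always leg minus dorsal. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

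Probes were named through the accession, symbol, gene ID or synonym in the array files, looked up in a reference gene table of assembly GRCg7b, which was used for names only. A name was found for 28741 probes, 11013 of them by accession, 12080 by symbol, 1386 by gene ID, 533 by synonym and 3729 by the name in the array files alone; 14862 probes had none. Positions are those of the array files, on galGal3, for 41890 probes. A gene with several tested probes was represented by the probe with the highest mean over the 8 arrays, which gave 11766 named genes. Keratins and other families with closely related members can share probe targets, and cross-hybridisation between paralogs was not measured.

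The tests, the lists of genes and the rule for naming genes were fixed before the data were examined. There were 31 lists of skin, position, signalling and cell type genes with 1156 written members, of which 961 matched a named gene in the files; one further rule put every gene described as a feather, scale, claw or beta-keratin into the beta-keratin list. Lists with at least 5 tested members, 30 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it stood camera with an estimated correlation and limma's fry. After the values had been seen, an exact two-sided permutation test of each list's mean over its members was added; with 70 labellings of 8 samples its smallest possible p is 0.0286. The naming rule took up to 12 genes per direction past the threshold, up to 4 members of each list with the smallest p, and, where fewer than 10 genes passed, the 10 genes with the smallest p. The genes printed are a subset of these, picked after their values were seen; PITX1 lies outside the rule and was likewise added. One gene that the rule names is not reported here.

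Probes well above background on all 4 arrays of one site and on none of the other were counted. Their fold is a lower bound: the mean of the detected site against the mean, per array of the other site, of the higher of the lowest signal among probes well above background and the probe's own signal.

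The same comparison was repeated with normexp background correction (offset 50), quantile normalization, median scaling, the deposited log2 values, no filter and a stricter filter on dim probes, the replicate number as a block, a variance trend with robust estimation, array weights, a mean over the probes of a gene, another detection flag, and each sample left out in turn. Slide and scan could not be entered as blocks, since all dorsal skin arrays lay on 1 slide and scan and all leg skin arrays on another, so that slide and site cannot be told apart. Random lists matched on brightness were also drawn and are not reported. Fits without dorsal skin samples 1 and 4, and with the alpha-keratin score as a covariate, were added after the values had been seen. A list's score in a sample is the mean, over its tested members, of the deviation of log2 signal from each member's mean over the 8 samples.

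The fit was tested on simulated data of 35499 probes with the spread of these arrays, each probe drawn independently. Of probes changed by 1, 2 and 3 on the log2 scale, 13.4%, 58.2% and 75.8% were recovered, and 7 unchanged probes were called. Camera called the simulated shifted list and 0 of 30 unshifted lists. The simulated probes were independent, while estimated inter-gene correlations in the real lists reached 0.86 (cell cycle). The simulation therefore does not show how often camera calls unshifted lists of correlated genes.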

Results

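Messenger RNA was profiled in dorsal skin and leg skin of 9-week-old chickens, with 4 samples per site on 8 one-colour arrays. The series set out to find pathways and genes that differ between skin of the back and of the leg. Between 75.5% and 89.3% of 43603 probes were well above background on each array, and 35516 probes were tested. Differences are given as leg minus dorsal on the log2 scale, with the standard error (SE) of the fit and 4 samples per site.

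Leg skin had higher signal than dorsal skin for keratins and for other genes of the epidermis, the outer layer of the skin. Beta-keratins are the hard structural proteins of feathers, scales and claws. Of the 26 members of their list, some of them probes without a gene name, 25 were higher, with a median difference of 3.90, or 2.36 without leg skin sample 4. All 14 alpha-keratins, the filament proteins of epidermal cells, were higher, with a median of 2.61, which became 1.48 without dorsal skin sample 4 and 0.43 without dorsal skin samples 1 and 4. Camera called the lists of blood vessels, macrophages, nerves and the respiratory chain lower in leg skin. In the vessel, macrophage and nerve lists the scores of the sites overlapped. Camera also called the dermal matrix list lower, though only leg skin samples 1 and 2 scored below the dorsal samples. These are calls on lists that were all lost with an estimated inter-gene correlation (adjusted p = 0.469 for both keratin lists and 0.469 to 0.699 for the lower lists), and no single gene passed the test.

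Limma called 0 of 35516 probes and 0 of 11766 named genes at an adjusted p of 0.05, in either direction, and 0 with at least a 2-fold difference. The smallest adjusted p was 0.192. At an unadjusted p under 0.05, limma gave 4407 probes, 12.4% of those tested, where 5% would be given by chance. Of these, 2709 were higher and 1698 lower in leg skin, and 1979 differed by at least 2-fold. In 973 named genes, or 8.27%, the 4 leg samples all lay on one side of the 4 dorsal samples, against 2.86% by chance. That 2.86% is an average over all splits of the samples. The count of 973 was not set against other splits, so it does not show that site stands out. Without dorsal skin sample 1 the 4407 probes became 2339, and without leg skin sample 1 they became 2472. Unless another value is given, each gene whose difference between sites is printed below had an adjusted p of 0.373. At each site all arrays lay on a slide of their own, so slide and site cannot be told apart.

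Of the 30 lists tested, camera called 15, 5 of them higher and 10 lower in leg skin. With an estimated inter-gene correlation 0 of the 30 passed, the smallest adjusted p being 0.469, and with limma's fry 0 passed, with a smallest adjusted p of 0.133 for a shift in one direction and 0.0631 for changes in either. By exact permutation of the sample labels, 5 lists (alpha-keratins, beta-keratins, epidermal barrier, mitochondrial respiration and Notch) reached the smallest p this design allows, 0.0286, and 0 passed after adjustment (adjusted p = 0.171). No member of any list passed over all probes tested. Adjusted over the list alone, 2 members were higher (FGF9 and SHH) and 7 lower in leg skin (TEK and SOX18 of the endothelial list, 3 of the Schwann cell list, HOXB8 and HOXD8). Each of these 9 was so called in 4 to 14 of the 19 alternatives, and with 1 sample left out 1 to 6 of the 9 were called. The counts of higher and lower members themselves became 1 and 2, 27 and 2, 35 and 4, and 5 and 32 without dorsal skin samples 1 to 4 in turn, and 16 and 3, 16 and 4, 2 and 15, and 14 and 3 without leg skin samples 1 to 4.

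Beta-keratins were higher in 25 of 26 members. The list's shift had an adjusted p = 3.48e-08 by camera, and adjusted p = 0.469 with an estimated correlation. The beta-keratin gene LOC426957 on chromosome 27 (galGal3 990326 to 990385) stood at -3.22 ± 0.959 (SD, n = 4) in dorsal skin and 1.73 ± 3.22 (SD, n = 4) in leg skin, a difference of 4.95 (SE 1.45). The feather keratin F-KER and LOC769186, both on chromosome 25, differed by 4.49 (SE 1.24) and 4.49 (SE 1.17). All 4 leg samples were above all 4 dorsal samples for each of these genes. The difference was uneven among the leg samples: the list's mean score, relative to the 8 samples' mean, was -0.43 and -0.38 in leg samples 1 and 2, 1.97 in sample 3 and 4.76 in sample 4, against -2.15, -0.94, -1.11 and -1.72 in dorsal samples 1 to 4. Without leg skin sample 4 the median difference was 2.36. The array of that sample also stood apart from the other 7, with 89.3% of probes well above background against 75.5% to 82.0%, a negative control SD of 1.63 against 2.13 to 2.70, and 1150 spots given a surrogate value against 3670 to 5643. Beta-keratin genes are close copies of one another, so a probe may read several of them.

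Alpha-keratins were called by camera with an adjusted p = 4.22e-05 (adjusted p = 0.469 with an estimated correlation). KRT9 differed by 5.74 (SE 2.09), KRT23 by 3.96 (SE 1.43), KRT13 by 3.91 (SE 1.55, adjusted p = 0.386) and KRT8 by 3.14 (SE 1.13). Of 26 genes of the epidermal barrier and of epidermal differentiation, 22 were higher in leg skin, with a median of 1.95 and an adjusted p = 9.68e-08 (adjusted p = 0.469 with an estimated correlation). Among them were FOXN1, a transcription factor of keratinocytes, by 2.43 (SE 0.557), the tight junction gene CLDN1 by 1.99 (SE 0.561), the plakin PPL by 1.13 (SE 0.308), and DLX3, detected on 3 of 4 dorsal arrays, by 2.76 (SE 0.807). Both lists were low in dorsal samples 1 and 4. The alpha-keratin score was -2.63 and -4.06 in these, 0.76 and 0.78 in dorsal samples 2 and 3, and 0.93 to 1.56 in the leg samples. KRT9 accordingly stood at 0.07 ± 4.80 (SD, n = 4) in dorsal skin and 5.81 ± 0.503 (SD, n = 4) in leg skin. Without dorsal samples 1 and 4, the median differences were 0.43 for alpha-keratins, 0.64 for the barrier list and 3.60 for beta-keratins, and all 3 lists were still called by camera. In that fit KRT9, KRT23, KRT13, KRT8, CLDN1 and DLX3 differed by 1.61, 1.32, 0.91, 0.97, 0.97 and 1.42. The count of probes at an unadjusted p under 0.05 became 1421. Without dorsal skin sample 4 alone, the medians were 1.48 for alpha-keratins and 1.24 for the barrier list. With the alpha-keratin score as a covariate, the barrier list had an adjusted p = 0.0615 by camera, and the count of probes became 643. Over the alternatives the barrier list's adjusted p ran from 5.28e-09 to 0.0615. Its median, less each setting's shift of all genes, ran from 0.04 to 2.38.

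**Figure D1:**
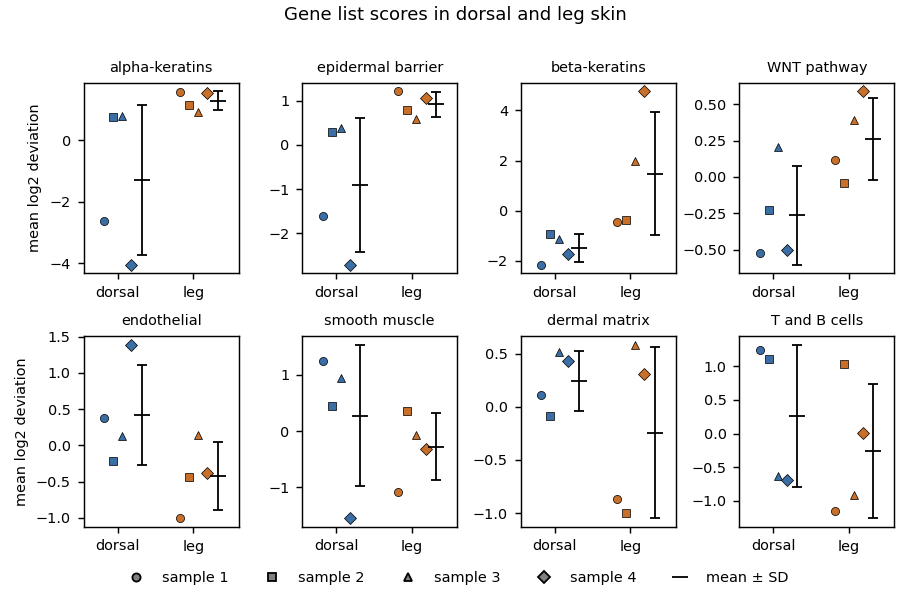
Mean log2 deviation of the members of 8 gene lists in each sample (y axis, log2 units relative to the mean of the 8 samples) for dorsal and leg skin; each point is 1 sample and bars are mean ± SD, n = 4. Alpha-keratin scores were -2.63 and -4.06 in dorsal samples 1 and 4, and beta-keratin scores were 1.97 and 4.76 in leg samples 3 and 4.

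Among the signalling lists of skin appendages, camera called the WNT pathway higher in leg skin. Of 51 genes of the WNT pathway, 32 were higher, with a median of 0.34 and an adjusted p = 0.00314 by camera (adjusted p = 0.469 with an estimated correlation). They included the receptor FZD10 by 2.12 (SE 0.546, detected on 3 of 4 dorsal arrays), the ligand WNT3 by 2.32 (SE 0.683) and the receptor LGR4 by 1.57 (SE 0.445). The WNT score was lowest in dorsal samples 1 and 4, at -0.53 and -0.51. When these were left out, the 3 genes differed by 0.89 (LGR4) to 1.48 (WNT3). Without leg skin sample 3 this list had an adjusted p = 0.0930, and over the alternatives it ran from 1.75e-04 to 0.0930. The median was 0.17 without leg skin sample 4. Sonic hedgehog, SHH, on chromosome 2 (galGal3 8024953 to 8025012), stood at -3.64 ± 0.155 (SD, n = 4) in dorsal skin and -2.06 ± 0.733 (SD, n = 4) in leg skin, a difference of 1.58 (SE 0.345), while 6 of 11 Hedgehog pathway genes were higher (adjusted p = 0.430). FGF9 on chromosome 1 (galGal3 182656482 to 182656541) was detected on 2 of 4 dorsal and all 4 leg arrays and differed by 1.32 (SE 0.275), a size that rests in part on dorsal signals near background. The FGF list of 28 genes had a median of -0.27, a mean of 0.12 and a test direction of higher (adjusted p = 0.840), with SPRY1 at 1.05 (SE 0.311) and ETV5 at 0.59 (SE 0.210). Its test direction turned without leg skin sample 3 or 4, and its median ran from -0.34 to 0.02 with 1 sample left out. The retinoid list of 19 genes likewise had a median of -0.20, a mean of 0.07 and a test direction of higher (adjusted p = 0.822), with CYP26B1, which breaks down retinoic acid, at 2.29 (SE 0.741; 1.21 without dorsal samples 1 and 4) and RARRES1 at -1.25 (SE 0.402). Its test direction turned without dorsal skin sample 1 or 2 or leg skin sample 3 or 4, and its median ran from -0.32 to 0.03 with 1 sample left out.

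Other signalling lists were not called. Notch genes were higher in 12 of 17 (median 0.27, adjusted p = 0.127), with DLK1 at 1.30 (SE 0.381; 0.83 without dorsal samples 1 and 4). Ectodysplasin pathway genes were higher in 8 of 10 (median 0.32, adjusted p = 0.0513); this list had adjusted p = 0.0310 without dorsal skin sample 1, 0.0450 without dorsal skin sample 3 and 0.0432 without leg skin sample 3, within 0.0310 to 0.377 over the alternatives, and its median was 0.63 without dorsal skin sample 3. BMP and TGF-beta genes were higher in 17 of 46 (median -0.25, adjusted p = 0.143), with BMP2 at 0.81 (SE 0.267) and the inhibitor SMAD7 at -0.73 (SE 0.210). That list had adjusted p = 0.0337 without leg skin sample 3 and 0.0261 without leg skin sample 4, within 0.0261 to 0.608. With 1 sample left out its median ran from -0.39 without leg skin sample 3 to -0.09 without leg skin sample 1, and that of the Notch list from 0.15 without leg skin sample 1 to 0.43 without dorsal skin sample 4.

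Camera called the lists of the dermis and its vessels and nerves lower in leg skin, and no member passed over all probes tested. Endothelial markers were higher in 2 of 25, with a median of -0.89 and an adjusted p = 1.06e-07 (adjusted p = 0.469 with an estimated correlation). The angiopoietin receptor TEK differed by -1.23 (SE 0.259), the transcription factor SOX18 by -1.48 (SE 0.325) and PODXL by -0.93 (SE 0.332; -0.56 without dorsal samples 1 and 4). The endothelial median was -0.45 without dorsal skin sample 4, and the list had an adjusted p = 0.0806 with the alpha-keratin score as a covariate, within 5.83e-09 to 0.0806 over the alternatives. Less each setting's shift of all genes, its median ran from -1.09 to -0.12. The endothelial score of leg skin sample 3 was 0.14, above dorsal skin samples 2 and 3 at -0.22 and 0.13. Dermal matrix genes were higher in 7 of 51 (median -0.50, adjusted p = 2.33e-04; adjusted p = 0.699 with an estimated correlation). The matrix score was -0.87, -0.998, 0.58 and 0.31 in leg samples 1 to 4, and 0.11, -0.09, 0.52 and 0.43 in dorsal samples 1 to 4. Only leg samples 1 and 2 thus lay below the dorsal samples. The basement membrane collagens COL4A1 and COL4A2 differed by -1.16 (SE 0.286) and -1.32 (SE 0.376) and the elastic fibre gene FBLN5 by -1.40 (SE 0.458), while COL14A1 went the other way by 1.08 (SE 0.364; 0.56 without dorsal samples 1 and 4). The matrix list had an adjusted p = 0.138 without leg skin sample 2, within 1.50e-08 to 0.138 over the alternatives. Its median was -0.32 without leg skin sample 1, -0.12 without sample 2 and -0.84 without sample 3. Schwann cell and nerve markers were higher in 3 of 19 (median -0.62, adjusted p = 0.00258; adjusted p = 0.469 with an estimated correlation), with UCHL1 at -1.75 (SE 0.382) and S100B at -1.24 (SE 0.330, detected on 3 of 4 leg arrays). The median of this list was -0.32 without leg skin sample 2 and -0.93 without leg skin sample 3. Its score in leg skin sample 4 was 0.061, above dorsal skin sample 4 at 0.045.

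Smooth muscle markers were higher in 1 of 28 (median -0.51, adjusted p = 0.00394; adjusted p = 0.707 with an estimated correlation), with ACTA2 at -1.50 (SE 0.485) and RGS5 at -0.98 (SE 0.394, adjusted p = 0.386; -0.57 without dorsal samples 1 and 4). Its score was -1.55 in dorsal sample 4 and 0.45 to 1.25 in the other dorsal samples. The list was not called without dorsal skin sample 1 (adjusted p = 0.0969), dorsal skin sample 3 (0.0897) or leg skin sample 1 (0.0944), within 1.68e-14 to 0.0969 over the alternatives. The medians were -0.20, -0.32 and -0.26, and -1.25 without dorsal skin sample 4. Skeletal muscle markers were higher in 10 of 40 (median -0.20, adjusted p = 0.253; 0.00841 without dorsal skin sample 4, within 0.00841 to 0.733), and their median ran from -0.45 without dorsal skin sample 4 to -0.06 without dorsal skin sample 1. Cartilage, bone and tendon genes were higher in 10 of 25 (median -0.05, adjusted p = 0.813). The test direction turned without dorsal skin sample 2 or 3 or leg skin sample 1 or 2, and the median ran from -0.21 to 0.12 with 1 sample left out.

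Camera also called the 4 immune and blood lists lower, and no member passed over all probes tested. The scores of the sites overlapped in all 4. For macrophages and granulocytes leg sample 2 scored 0.33, above dorsal samples 3 and 4 at -0.20 and 0.20. For blood dorsal sample 2 scored -0.39, below leg samples 1, 2 and 4 at -0.38, -0.31 and -0.24. T and B cell scores were 1.25, 1.12, -0.63 and -0.69 in dorsal samples 1 to 4. In leg samples 1 to 4 they were -1.16, 1.03, -0.92 and 0.002. Interferon scores were 1.02, 0.98, -0.61 and -0.28 in dorsal samples, and -0.18, 0.81, -1.36 and -0.39 in leg samples. In the T and B cell and interferon lists dorsal samples 1 and 2 stood above dorsal samples 3 and 4. Macrophage and granulocyte markers were higher in 5 of 39 (median -0.57, adjusted p = 1.04e-04; adjusted p = 0.546 with an estimated correlation), with MRC1 at -1.28 (SE 0.446), the cathepsin CTSS at -0.59 (SE 0.211) and avidin, AVD, at -2.19 (SE 0.768); without leg skin sample 1 the median was -0.34. Interferon response genes were higher in 2 of 28 (median -0.57, adjusted p = 0.00200; adjusted p = 0.699 with an estimated correlation), with IRF1 at -0.87 (SE 0.449, adjusted p = 0.461) and B2M at -0.54 (SE 0.300, adjusted p = 0.490). This call was lost without dorsal skin sample 2 (adjusted p = 0.0835) and leg skin sample 3 (0.146), within 4.73e-11 to 0.146, and the median was -0.33 without dorsal skin sample 1 and -0.26 without leg skin sample 3. T and B cell markers were higher in 4 of 33 (median -0.70, adjusted p = 0.0150; adjusted p = 0.707 with an estimated correlation), with GZMA at -1.58 (SE 0.744, adjusted p = 0.429) and, against the list's direction, GATA3 at 2.39 (SE 0.774), a factor that keratinocytes also express. This call was lost without dorsal skin sample 1 (adjusted p = 0.247), dorsal skin sample 2 (0.299), leg skin sample 1 (0.195) or leg skin sample 3 (0.156), within 3.16e-05 to 0.299, and its median ran from -0.34 without leg skin sample 1 to -1.14 without leg skin sample 2; without dorsal skin samples 1, 2 and 3 in turn it was -0.36, -0.41 and -1.08. Blood and haemoglobin genes were higher in 2 of 20 (median -0.73, adjusted p = 0.00258; adjusted p = 0.670 with an estimated correlation), with HBA1 at -1.65 (SE 0.655, adjusted p = 0.386) and HEMGN at -1.37 (SE 0.443). Without dorsal samples 1 and 4, differences were -0.53 for IRF1, -0.21 for B2M, -0.55 for GZMA, 1.06 for GATA3, -0.77 for HBA1 and -0.65 for HEMGN. The blood list's median was -1.09 without dorsal skin sample 2 and -0.41 without dorsal skin sample 4, and with the alpha-keratin score as a covariate its direction was higher (adjusted p = 0.949), within 1.93e-04 to 0.949.

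Camera called the genes of mitochondrial respiration lower in leg skin. Of 48, 1 was higher, the median was -0.25 (-0.93 with normexp background correction, after that setting's shift of all genes was taken off) and the adjusted p = 5.67e-08 (adjusted p = 0.469 with an estimated correlation), with CYCS at -0.65 (SE 0.190) and UQCRB at -0.47 (SE 0.149). All 61 ribosomal protein genes were higher by a median of 0.15 (adjusted p = 2.81e-05; adjusted p = 0.685 with an estimated correlation), but with normexp background correction the list's direction was lower. RPL29 differed by 0.24 (SE 0.142, adjusted p = 0.517). Cell cycle genes were higher in 7 of 54 (median -0.21, adjusted p = 0.170). That list had adjusted p = 0.0450 without dorsal skin sample 3, 2.12e-06 without dorsal skin sample 4 and 8.08e-04 without leg skin sample 2, within 3.50e-11 to 0.890. Its direction turned to higher without dorsal skin sample 2 (44 of 54 higher, median 0.14) and without leg skin sample 3 (median 0.07), and its median was -0.61 without dorsal skin sample 4. Heat shock and immediate early genes, which respond to handling stress, were higher in 16 of 38 (median -0.08, adjusted p = 0.805). With normexp background correction camera called this list lower (adjusted p = 1.89e-04), within 1.89e-04 to 0.896 over the alternatives. The test direction turned without leg skin sample 1.

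Fat and pigment genes were mixed. Adipocyte markers were higher in 7 of 25 (median -0.49, adjusted p = 0.167), with ADIPOQ at -1.23 (SE 0.428), THRSP at -0.95 (SE 0.399, adjusted p = 0.396) and GPAM the other way at 1.35 (SE 0.360). Without dorsal samples 1 and 4 the last 2 differed by -0.35 and 0.81. Lipid synthesis genes were higher in 26 of 44 (median 0.15, adjusted p = 0.0797), with the fatty acid elongases ELOVL6 at 1.96 (SE 0.635) and ELOVL7 at 2.01 (SE 0.658). Both were lowest in dorsal samples 1 and 4, as was the lipid score (-0.63 and -0.67), and differed by 0.75 and 0.89 without them. The adipocyte list had adjusted p = 0.0416 without dorsal skin sample 1 and 0.0499 without dorsal skin sample 2, within 9.70e-04 to 0.752, and the lipid list 0.00144 without dorsal skin sample 2 and 0.0346 without leg skin sample 2, within 0.00144 to 0.742. Melanocyte and pigment genes were higher in 12 of 19 (median 0.20, adjusted p = 0.0728), with PMEL at 2.09 (SE 0.776) and GPNMB at 3.85 (SE 1.45, adjusted p = 0.374), both detected on 3 of 4 dorsal arrays. GPNMB stood at -6.59 and -3.35 in dorsal samples 1 and 4 and differed by 1.23 without them. TYR was detected on 1 of 4 dorsal and 3 of 4 leg arrays. This list had adjusted p = 0.00230 without dorsal skin sample 4 and 0.0125 without leg skin sample 2, within 8.05e-04 to 0.909. With 1 sample left out the medians ran from -0.53 to -0.19 for adipocyte markers, 0.06 to 0.24 for lipid synthesis and 0.11 to 0.56 for pigment genes.

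Of the lists of genes that mark position along the body, camera called the HOX genes of paralogue groups 1 to 7 lower in leg skin. They were higher in 2 of 14 (median -0.41, adjusted p = 0.00543; adjusted p = 0.469 with an estimated correlation), with HOXD4 at -0.54 (SE 0.194) and HOXD3 the other way at 1.16 (SE 0.318; 0.63 without dorsal samples 1 and 4). This list had a median of -0.27 and an adjusted p = 0.0550 without dorsal skin sample 4, within 1.92e-04 to 0.133 over the alternatives. HOX genes of groups 8 to 13 were higher in 4 of 9 (median -0.11, adjusted p = 0.468), with an adjusted p = 0.0434 with the alpha-keratin score as a covariate, within 0.0434 to 0.810 over the alternatives, and a median from -0.70 to 0.31. The 0.31 came with no filter on dim probes. In that setting 11 of 17 were higher and camera's test direction was higher (adjusted p = 0.446). HOXB8 differed by -1.09 (SE 0.317) and HOXD8 by -0.71 (SE 0.213), each lower in all 4 leg samples than in all 4 dorsal samples. The other probes of HOXB8, HOXD8, HOXD4 and HOXD3 differed by -0.35, -0.80, -0.17 and 0.55. Limb identity genes were higher in 11 of 20 (median 0.04, adjusted p = 0.590), with MSX2 at 1.82 (SE 0.667) and TBX2 at -0.73 (SE 0.302, adjusted p = 0.391), or 0.87 and -0.32 without dorsal samples 1 and 4. This list's test direction turned without dorsal skin sample 4 (median -0.15), and its median ran up to 0.21 with 1 sample left out. PITX1, a hindlimb factor, differed by -0.49 (SE 0.467, adjusted p = 0.699; -0.28 without dorsal samples 1 and 4), and another probe of it went the other way by 0.40.

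**Figure D2:**
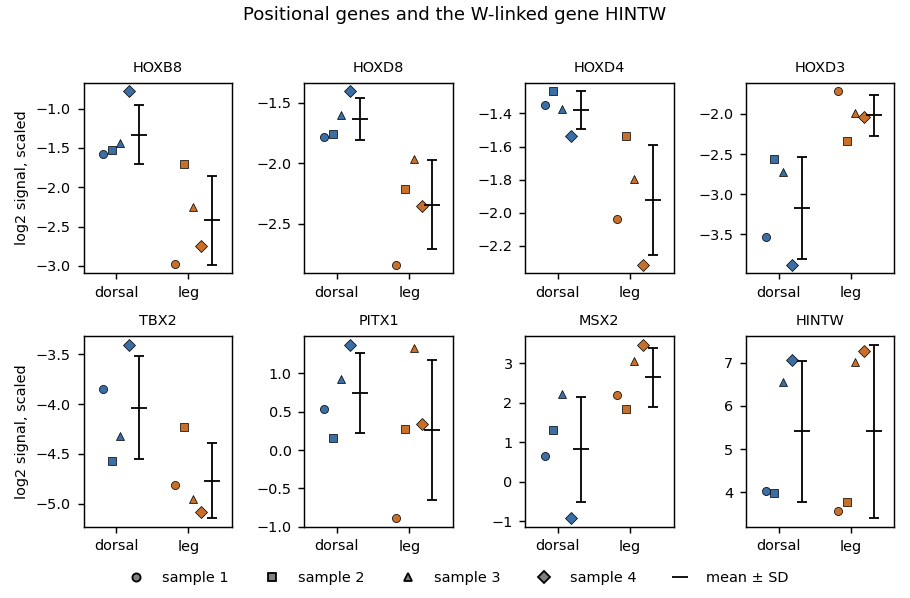
Log2 signal relative to each array's 75th percentile (y axis) of 7 positional genes and of the W-linked gene HINTW in dorsal and leg skin; each point is 1 sample and bars are mean ± SD, n = 4. HOXB8, HOXD8 and HOXD4 were lower in all 4 leg samples than in all 4 dorsal samples, and HINTW was higher in samples 3 and 4 of both sites than in samples 1 and 2. For HOXD4 the nearest samples almost met, at -1.5381 in leg sample 2 and -1.5378 in dorsal sample 4.

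The 10 named genes with the smallest p, none of which passed, included 9 that were higher in leg skin. The innate immune receptor TLR15 on chromosome 3 (galGal3 2945875 to 2945934) stood at -2.52 ± 0.566 (SD, n = 4) in dorsal skin and -0.76 ± 0.0790 (SD, n = 4) in leg skin, a difference of 1.76 (SE 0.275). SGIP1, LOC428515 and LOC771266 were higher but were each detected on 1 of 4 dorsal arrays, so the sizes of their differences rest on dorsal signals near background and are not given. PYROXD2 differed by 0.90 (SE 0.172), LOC425562 by 0.78 (SE 0.152), CCSER1 by 0.87 (SE 0.179) and KLHL7 by 0.96 (SE 0.202); FGF9 is given above. DACT1, a regulator of WNT signalling, was the gene lower in leg skin, by -1.12 (SE 0.217). For each of the 10 the 4 leg samples lay on one side of the 4 dorsal samples.

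**Figure D3:**
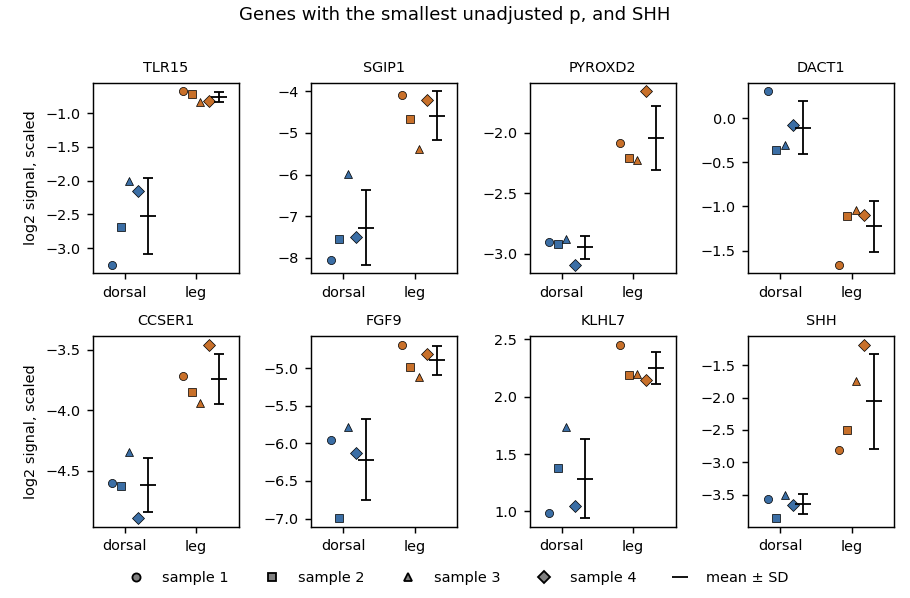
Log2 signal relative to each array's 75th percentile (y axis) of 7 of the 10 named genes with the smallest p, and of SHH, in dorsal and leg skin; each point is 1 sample and bars are mean ± SD, n = 4. In each panel the 4 leg samples lie on one side of the 4 dorsal samples (SGIP1 was detected on 1 and FGF9 on 2 of the 4 dorsal arrays), with none of the differences past an adjusted p of 0.05.

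Presence at a single site was rare. Probes well above background on all arrays of one site and on none of the other numbered 3 for leg skin and 8 for dorsal skin, and 30933 probes were well above background on all 8 arrays. The 3 leg probes had no gene name. The 8 dorsal probes included 1 of the 3 probes of S100B, at least 1.67-fold higher in dorsal skin, with another probe of that gene detected in both sites, and the genes LOC416215 and LOC771492, at least 1.55-fold and 1.16-fold higher. The W-linked list had 4 measured members, too few for a list test, and HINTW differed by 0.00 (SE 1.12, adjusted p = 1.00) between sites, with its 7 probes between -0.13 and 0.09.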

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

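In 204 groups of 4 samples (list scores, named genes and array measures at each site), the gap of the highest or lowest sample to its nearest neighbour was compared with the group's whole range. The ratio exceeded Dixon's critical value for 4 samples in 4 groups, where about 10.2 would do so by chance. The 4 are given as values on the log2 scale, with no explanation tested.

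CTSS, a cathepsin of macrophages, was lowest in dorsal skin sample 3 at 4.52, with the other dorsal samples at 5.19 to 5.32 (ratio 0.838). DACT1, a regulator of WNT signalling, was lowest in leg skin sample 1 at -1.66, with the others at -1.11 to -1.04 (ratio 0.879). KLHL7 was highest in leg skin sample 1 at 2.45, with the others at 2.15 to 2.20 (ratio 0.830). The plakin gene PPL was highest in dorsal skin sample 3 at 6.13, with the others at 4.88 to 5.004 (ratio 0.898).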

How the results depend on the processing

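The fits without dorsal skin samples 1 and 4, with the alpha-keratin score as a covariate, and the exact permutation of list scores were chosen after seeing the data; the other alternatives were planned. The count of 0 probes and 0 genes past an adjusted p of 0.05 was the same in every alternative run. Probes at an unadjusted p under 0.05, 4407 as reported, numbered 1421 without dorsal skin samples 1 and 4, where fewer samples were fitted, 643 with the covariate, and 2339 to 5222 with 1 sample left out; normexp gave 3018 and no filter 5955. With an unadjusted p in place of the adjusted one, 1979 probes differed by at least 2-fold. The other detection flag gave 24 probes found at 1 site in place of 11. Camera called 13 to 18 lists over these settings, 0 with an estimated correlation and 0 by exact permutation.

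Normexp moved the median of all tested probes from -0.03 to 0.40, and that of the probes that represent genes from -0.03 to 0.37. Its values are given after the first shift was taken off for single genes, and the second for lists. It turned the ribosomal list to -0.54, the ETV5 log2 difference to -0.0833, HEMGN to 0.0704, RPL29 to -0.52, S100B to 0.11 and TBX2 to 0.22. With no shift taken off, normexp gave 2319 probes higher and 699 lower at an unadjusted p under 0.05, against 2709 and 1698, a balance that the shift itself moves. It also moved the medians of mitochondrial respiration to -0.93, dermal matrix to -0.92, interferon response to -1.12, smooth muscle to -1.15 and alpha-keratins to 1.39, and made that of the barrier list over 1.5 times smaller; array weights moved those of the Schwann cell list to -0.31 and dermal matrix to -0.12, and made that of smooth muscle over 1.5 times larger. With the covariate the blood list was at 0.0325. The cause was not tested in any of these. Camera's call was also lost with normexp for the WNT, Schwann cell and first HOX lists (adjusted p = 0.0818, 0.145 and 0.133) and gained for the adipocyte, cell cycle, heat shock and melanocyte lists, and was lost without the filter for WNT (0.0635), and with array weights for the dermal matrix (0.0809). Of 599 list values, 528 stayed on their side of the threshold, 34 lost a call, 35 gained one and 2 reversed; in 31 the direction differed where neither value passed. Of 1320 values for 70 named genes, 5 reversed, and none passed.

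With the replicate block, limma again called 0 probes and camera the same 15 lists, and 4500 probes had an unadjusted p under 0.05 (2337 higher and 2163 lower). Adjusted over the list alone, the block gave 8 members higher (7 beta-keratins and SHH) and 2 lower (1 each of the Schwann cell and first HOX lists) in place of 2 and 7, with 2 of those 9 among them; TEK, SOX18, HOXB8, HOXD8, FGF9, UCHL1 and S100B were not called. Over all alternatives these counts ran from 1 to 35 higher and from 0 to 32 lower, with 17 beta-keratins higher both with normexp and with array weights. Equal numbers correlated at 0.004, 0.467, 0.244 and 0.218 over the deviations from the site means, and unequal numbers from -0.418 to 0.333; 4 of 8 samples correlated best with their own number. Slide and scan blocks were not run, since each site had its own. Dim probes limit the comparison: 3570 of 43603 probes were well above background on none of the arrays.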

Other observations

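The tests of explanations were all chosen after the results they bear on had been seen, and so was the split of samples 1 and 2 from samples 3 and 4.

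Samples differed by number in a way that site did not explain. The W-linked gene HINTW stood at 4.02 and 3.98 in dorsal skin samples 1 and 2 and at 6.55 and 7.07 in dorsal skin samples 3 and 4, and at 3.57, 3.78, 7.02 and 7.27 in leg skin samples 1 to 4. SPIN1L, also W-linked, stood at 0.69, 0.34, 1.45 and 1.80 in dorsal skin and at 0.96, 0.42, 1.82 and 1.64 in leg skin. Of the other 2 W-linked genes measured, ATP5A1W differed little by number in dorsal skin (2.40, 2.40, 2.53 and 2.48) and more in leg skin (1.79, 2.08, 2.46 and 2.51), and HNRNPKL was lower in dorsal skin samples 3 and 4 (at most 0.90) than in samples 1 and 2 (at least 1.13) and lay at 1.00 to 1.07 in leg skin. When the 8 samples were split with numbers 1 and 2 against numbers 3 and 4, limma called 169 probes, the most of the 35 possible splits into 4 and 4, which is why this split was looked at.

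A candidate explanation for that split is the sex of the chickens, since female birds carry the W chromosome and a single Z. Of the 50 tested W probes 26 were called, or 52%, all of them higher in samples 3 and 4, and the median difference of 1455 Z probes was -0.45. Array position on the slide follows the same numbers, but it has no reason to spare autosomal probes, and of 30980 of these 0.245% were called, with a median difference of 0.003. The sex of the chickens was not given in the labels, and whether equal numbers mark the same chicken stays open.

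Epidermal genes were low in dorsal skin samples 1 and 4: 29 of 40 alpha-keratin and barrier genes were lower in both than in each of the other 6 samples. Of 9 array measures (share of probes well above background, 75th percentile and median of processed intensity, background, slope and R-squared of the spike-in fit, negative control SD, outlier spots and surrogate spots), 0 lay outside the range of the other 6 arrays in sample 1, which argues against poor array quality there, and 1 in sample 4, the median intensity at 148 against a lowest of 151, which leaves it open. A swap between sites would need a leg sample with a low alpha-keratin score, while the lowest was 0.93. In dorsal skin sample 1, a smaller share of epidermis in the piece of skin may explain it, since 0 of 4 dermal lists were lower than in the other samples by over 1 SD; in dorsal skin sample 4 that alone is argued against, since 1 of the 4, smooth muscle, stood at -1.60 from the mean of the other 6 samples while endothelial markers stood at 1.69. No biological explanation for single samples was tested, and a difference in dissection between sites cannot be told apart from one in tissue.

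The lowest beta-keratin score of leg skin samples 3 and 4 exceeded the highest of dorsal skin samples 2 and 3 by 2.90, while alpha-keratin scores differed by at most 0.77. These 2 leg samples were set apart after their beta-keratin scores were seen to be the highest. Dorsal skin samples 1 and 4 were the lowest of all samples on both scores, but by unlike amounts. Alpha-keratins stood at -2.63 and -4.06 there, against 0.76 and 0.78 in dorsal skin samples 2 and 3. Beta-keratins stood at -2.15 and -1.72, against -0.94 and -1.11. With amounts this unlike, the alpha-keratin gap does not set a bound on what more epidermis would do to beta-keratins. In leg skin samples 1 and 2 the same gap was 0.50 beside 0.80 for alpha-keratins. Leg skin sample 1 had the highest alpha-keratin and barrier scores, 1.56 and 1.21, but a beta-keratin score of -0.43. Leg skin sample 3 had the lowest of the leg samples, 0.93 and 0.59, with a beta-keratin score of 1.97. Leg skin sample 4 stood at 1.53, 1.06 and 4.76. These values argue against more epidermis as the source of the excess of leg samples 3 and 4 over leg samples 1 and 2. In leg samples 1 and 2, more epidermis and a rise of beta-keratins cannot be told apart. The bounds of 2.90 and 0.50 replaced a single test over all 4 leg samples, whose median difference of 3.60 had left the question open. No slide held both sites (0 slides), so an effect of the slide stays open, as do the array of leg skin sample 4, which stood apart in 5 of 9 measures, and a difference between the sites in growing feathers or scales, which the labels do not describe. The sex of the chickens, which may follow the numbers, stays open too. Beta-keratin scores were 1.97 and 4.76 in leg samples 3 and 4 against -0.43 and -0.38 in leg samples 1 and 2. Dorsal samples 1 to 4 showed no such split, at -2.15, -0.94, -1.11 and -1.72.

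Other splits of the samples set the site comparison in proportion. A count of 0 probes past an adjusted p of 0.05 is reached by any split, here all 35, so it tests nothing; the highest other, 169, came from numbers 1 and 2 against 3 and 4 and points to structure among the samples beyond site. The 4407 probes at an unadjusted p under 0.05 were reached by 4 of the 35 splits, site included, with the highest other at 6203 from that same split. The other splits that reached it, at 4731 and 5206, also set most samples numbered 1 and 2 against most numbered 3 and 4. Among splits with 1 sample of each number on each side, site gave the most, the next being 2731. Such splits are too few for a share under 0.05. The 15 lists called by camera were reached by 5 of the 35, with the others at 4 to 16. The 11 probes detected at 1 site were reached by 23 of the 35, with the highest other at 118. Over all 35 splits chance cannot be excluded for the last 3 counts, though splits that follow the numbers hold structure of their own.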
